A study of Mus musculus with 18 samples.

How the data were processed

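RNA was measured by sequencing in whole mammary gland tissue of 18 mice on a mixed C57BL/6Jx129 background, with lymph nodes excluded, per the labels' protocols. The mice were wild type (WT) or Cip2a-/-. Cip2a encodes an inhibitor of the phosphatase PP2A. For the treated mice, 1 mg of the carcinogen DMBA (7,12-dimethylbenz[a]anthracene) in oil was given by gavage once a week for 6 weeks, starting at 12 to 14 weeks of age. The 6 groups of 3 libraries were untreated glands, glands taken 2 weeks after the last dose, and tumour-free glands taken at the endpoint, when mice were sacrificed because of DMBA-induced tumours in any tissue, each in both genotypes. The age at the endpoint, the time since the last dose at the endpoint, litter, cage, oil-only treatment and sequencing date are not given in the sources used here. The effects of DMBA and of gavage in oil are therefore not separated here.

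The RNA was isolated with a NucleoSpin kit and libraries followed the TruSeq Stranded mRNA guide, per the labels' protocols. Reads were demultiplexed with bcl2fastq 2.17, and STAR 2.5.2b, Subread 1.5.1 and the mouse genome build mm10 are named, per the submitters' processing notes. The deposited values are raw read counts per gene symbol, 1 column per library, with an Entrez identifier beside most symbols, per the file headers. The annotation, the strand setting and the treatment of reads that map to several places are not given in the sources used here. Counts of genes with near-identical copies (ribosomal protein genes and their pseudogenes, immunoglobulin genes, Ifi202b and the other Ifi200 genes) or with a neighbour on the other strand are therefore uncertain. All values in the table were whole numbers of 0 or more, and total counts per library ranged from 16121743 to 24586404. Every column was matched to a library of the labels, with 0 columns unmatched. The column headers also hold a number per library, which is higher in every 2-week library than in any untreated or endpoint library. Cip2a-/- untreated library 2 comes closest to the 2-week numbers. What these numbers stand for is not given in the sources used here.

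The table held 23337 symbols, of which 23131 were matched to a RefSeq gene table, 21504 by Entrez identifier, 1623 by synonym and 4 by symbol. Transcript length and GC content were taken for 20985 genes by Entrez identifier and 1949 by name, and 403 had none. Coordinates are from the GRCm38 RefSeq annotation, the assembly also called mm10. The table lists Cip2a under its older symbol C330027C09Rik.

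Everything else was computed here from the counts. Counts were analysed with edgeR 4.0.16 in R 4.3.3: genes were kept by filterByExpr (minimum count 10, minimum total 15), which left 15482 genes, libraries were scaled by TMM, and a quasi-likelihood model with 1 term per group was fitted to all 18 libraries. Each contrast was tested with the quasi-likelihood F-test, and p-values were adjusted over all genes tested by the Benjamini-Hochberg method. A gene was called at an adjusted p under 0.05. CPM is the usual depth-scaled count after TMM scaling, and log2 CPM was computed with a prior count of 2. A floor of 3 reads, summed over a group's libraries, stands for a group with 0 reads. Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules.

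The comparisons fixed before the data were examined were Cip2a-/- against WT in each of the 3 conditions and averaged over them, 2 weeks after DMBA and the endpoint each against untreated within each genotype, the endpoint against 2 weeks averaged over the genotypes, and the interaction of genotype and DMBA at each time. The averages over genotypes of the 2-week and of the endpoint effect against untreated glands were added after the data were seen. Gene lists, 47 in number, were fixed in the same way. They hold markers of the cell types a gland sample can contain, pathways, p53 targets, genes induced through the aryl hydrocarbon receptor (the receptor for DMBA), PP2A subunits and inhibitors, and genes near Cip2a. Ribosomal protein genes, picked by a symbol pattern also fixed before, made 48 lists tested. Lists were tested with camera in limma 3.58.1 at the preset inter-gene correlation of 0.01, with adjustment over the lists within a comparison, and again with an estimated correlation and with fry. A score of a list is the mean over its genes of the log2 CPM centred per gene. A score difference is the difference of the group means of a score, computed with all libraries and, after the data were seen, without each library in turn. Scores were compared by exact two-sided permutation tests, whose smallest p for 3 libraries against 3 is 0.1.

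Genes were named by a rule fixed before the data were examined. It takes Cip2a first, then the 6 called genes with the largest increase and the 6 with the largest decrease among those with a mean of at least 5 CPM, a gene name rather than a clone name, and no overlap between the groups (chance gives non-overlap to 10% of genes for 3 against 3). It adds up to 18 members of lists that pass camera, and, where fewer than 6 genes were called, all of them and the 5 with the smallest p. Genes named outside the rule are said to be chosen after their values were seen. Results for some genes that the rule or the lists name are not reported here.

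Alternatives were size factors from median ratios (RLE), no low-count filter, DESeq2 1.42.0, limma voom with library quality weights, 1 surrogate variable from sva 3.50.0, the replicate number as a block, only the groups of a contrast, and each library left out in turn. Added after the data were seen were the scores of skeletal muscle, B cells and luminal progenitors as 3 covariates, joint removal of libraries that stood apart, and offsets from splines (5 degrees of freedom) on transcript length, on GC content and on both. The same libraries were regrouped in all 10 ways for 3 against 3, and in 60 ways, the real one included, for the averaged and interaction comparisons.

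The edgeR test was tested on simulated counts for the 15482 genes with 200 genes changed. For the untreated genotype comparison it recovered 15 of 100 genes changed 2-fold and 61 of 100 changed 4-fold, with 1 false call among 77. For the endpoint against 2 weeks it recovered 47 of 100 and 81 of 100, with 8 false calls among 136. In simulated data camera called the 1 shifted list and 1 of the other lists. All simulated counts were drawn gene by gene from a common mean profile, without correlation between genes. The rates of false calls therefore need not hold for the real libraries, whose glands differ in many genes together. The replicate numbers of the labels were checked for pairing and gave none, so no block is in the main model. Figures were drawn with matplotlib in Python 3.11.15. The mitochondrially encoded genes, also fixed as a list, had 0 symbols in the table and were not analysed here.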

Results

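Gene expression was measured in 18 mammary glands of WT and Cip2a-/- mice, untreated, 2 weeks after the last of 6 weekly doses of DMBA, or at the endpoint, with 3 libraries in each of the 6 groups. DMBA is a polycyclic aromatic hydrocarbon that induces mammary and other tumours and is activated by cytochrome P450 enzymes to DNA-damaging metabolites. The endpoint glands were free of tumour, while the mouse had a DMBA-induced tumour in some tissue. Total counts per library ranged from 16121743 to 24586404, and 15482 genes passed the low-count filter. At an unadjusted p under 0.05, chance gives 774 of these genes.

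Cip2a, named C330027C09Rik in the table (chromosome 16, 48994157 to 49019716), followed the genotype labels in all 18 libraries. WT glands had 1.42 ± 0.524 CPM untreated (SD, n = 3), 3.08 ± 0.245 CPM at 2 weeks and 3.23 ± 1.65 CPM at the endpoint. Cip2a-/- glands had 2 Cip2a reads in all in the untreated group and 0 reads in both treated groups. WT glands thus had 38.0 times the Cip2a level of Cip2a-/- glands untreated, with an exact 95% counting interval from 10.2 to 319. They had at least 61.2-fold more at 2 weeks and at least 66.4-fold more at the endpoint, each from the reads pooled over a group against a floor of 3 reads over the group. Of the 202 reads at the endpoint, 126 came from WT endpoint library 2, and the mean of the 3 CPM values there was 61.0 times the floor. The edgeR quasi-likelihood test called Cip2a lower at 2 weeks (adjusted p = 0.0281), at the endpoint (adjusted p = 0.0276) and averaged over the 3 conditions (adjusted p = 0.000325). In untreated glands alone the adjusted p was 0.568 with edgeR and 0.0263 with DESeq2. The fitted averaged log2 fold change of -7.63 is no bound, because it depends on groups with 0 reads. In WT glands Cip2a differed from untreated by a log2 fold change of 1.11 ± 0.54 (SE) at 2 weeks and 1.18 ± 0.54 at the endpoint, which did not pass the test (adjusted p = 0.953 and 0.415).

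**Figure D1:**
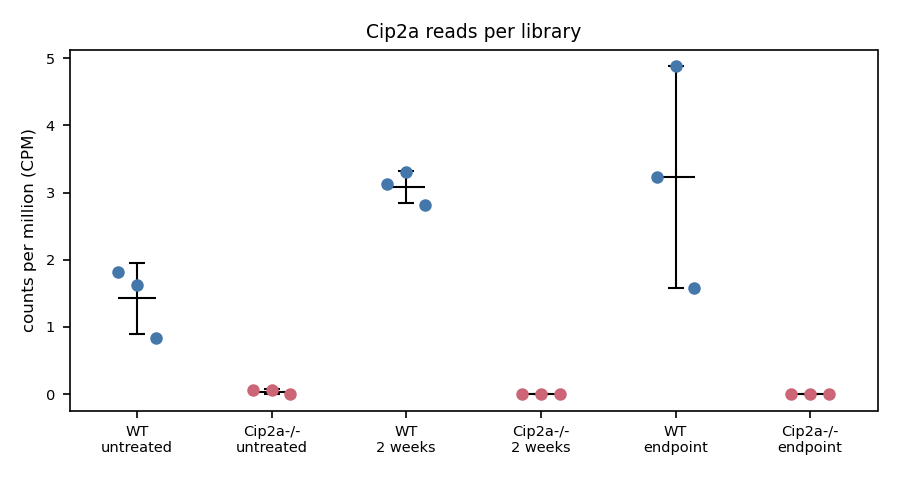
Cip2a level in CPM (y axis) in each of the 18 libraries by group (x axis), with WT in blue and Cip2a-/- in red. Horizontal marks are means and bars are 1 SD (n = 3), and the 9 Cip2a-/- libraries lie at 0.0598 CPM or lower while the 9 WT libraries lie at 0.831 CPM or higher.

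Markers of muscle, B cells, brown fat and epidermis differed widely between glands of the same group. Ckm, which encodes muscle creatine kinase, ranged from 0.929 to 6677 CPM among the WT endpoint glands and from 10.3 to 9288 CPM among the Cip2a-/- 2-week glands. The B cell marker score ranged from -2.54 to 5.10 in the first of these groups and from -3.17 to 2.48 in the second. In each group the score of lymph node stroma markers was highest in the same gland. It was 3.94 in WT endpoint library 1 and 1.84 in Cip2a-/- 2-week library 2. In WT endpoint library 3 it was -0.46 beside a B cell score of 1.12. Lymph nodes were excluded per the protocols, and whether some node tissue remained was not tested. WT endpoint library 1 had 5835 CPM of Ucp1, the brown fat uncoupling protein, against 0.929 and 0.190 CPM in the other 2 glands of its group. It had 4.37 CPM of the epithelial gene Epcam, against 62.9 CPM or more in the other libraries. The epidermal keratin gene Krt10 stood at 142 CPM in Cip2a-/- untreated library 3 and at 3.11 and 3.14 CPM in the other 2 glands of its group. The first principal component held 34.7% of the variance.

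**Figure D2:**
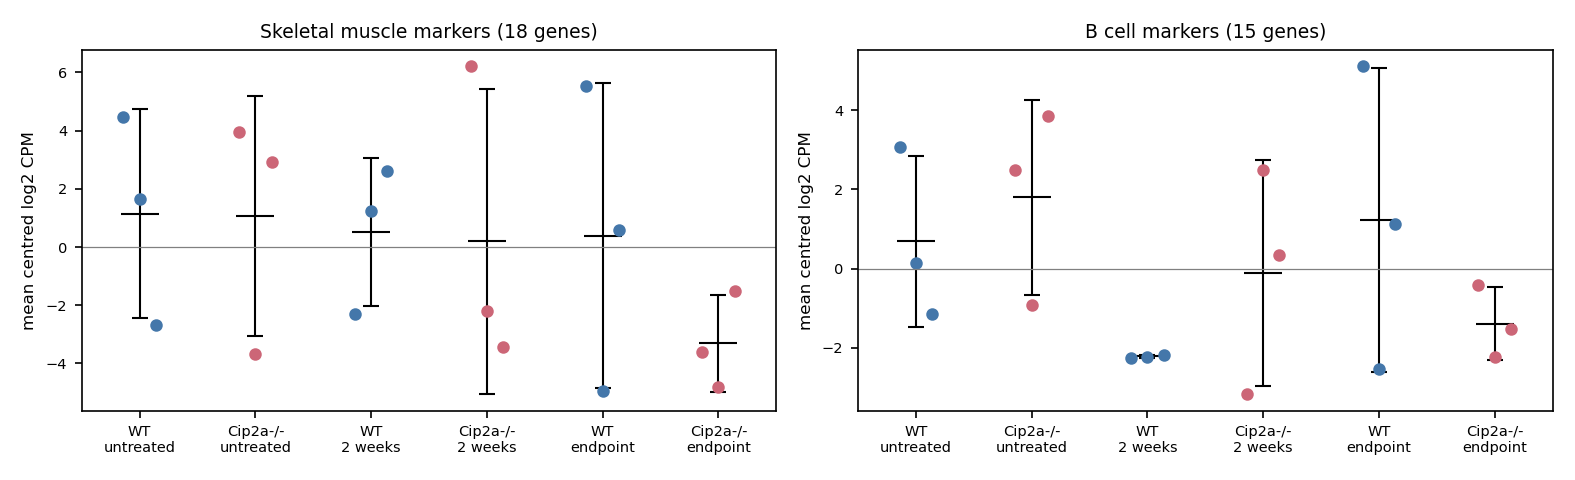
Scores of skeletal muscle markers (left) and B cell markers (right) per library, as the mean over genes of centred log2 CPM (y axis), by group (x axis). Points are libraries, marks are means and bars 1 SD (n = 3). The muscle score spans -3.45 to 6.21 within the Cip2a-/- 2-week group and -4.95 to 5.54 within the WT endpoint group.

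The loss of Cip2a in untreated glands was compared first. DNA replication and mitosis genes had higher fitted values in Cip2a-/- glands, with a median log2 fold change of 0.78 over 30 S phase genes controlled by E2F factors and 1.32 over 30 genes of the G2 and M phases. Hells, a chromatin remodeller active in dividing cells, stood at 5.98 ± 2.55 CPM in Cip2a-/- and 1.64 ± 0.327 CPM in WT glands, and the condensin subunit gene Ncapg2 at 9.20 ± 1.69 and 3.46 ± 0.705 CPM. This difference came from 2 of the 3 Cip2a-/- glands: library 1 had the lowest scores of the 6 untreated glands, -0.60 for the S phase list and -1.57 for the G2 and M list, while libraries 2 and 3 had 0.77 and 0.87, and 1.11 and 1.18. WT glands lay between -0.49 and 0.02, and between -1.07 and -0.19. T cell and B cell markers had medians of 0.93 and 0.80, with scores that overlapped between the genotypes. In library order the B cell score was 3.07, 0.15 and -1.14 in WT and 2.48, -0.93 and 3.85 in Cip2a-/- glands. The lymph node stroma score went with it, at 1.15, -0.33 and -0.88 in WT and 1.36, -0.81 and 2.79 in Cip2a-/- glands. Without Cip2a-/- untreated library 3 the score differences fell from 0.63 to 0.37 for the S phase list, from 0.91 to 0.44 for the G2 and M list, from 1.01 to 0.11 for T cells and from 1.11 to 0.09 for B cells. Camera called the E2F list (adjusted p = 6.13e-18; adjusted p = 0.613 with an estimated correlation) and the G2 and M list (adjusted p = 4.39e-16; adjusted p = 0.860 with an estimated correlation), as it did the T cell list (adjusted p = 0.00398) and the B cell list (adjusted p = 0.0486), both with adjusted p = 0.860 with an estimated correlation. No single gene passed: edgeR called 0 genes and 0 members of either cycle list adjusted over the list alone, with 352 genes at an unadjusted p under 0.05, while DESeq2 called 6 and voom called 0. The smallest p values after Cip2a were those of Atp6v0e2 (log2 fold change -0.96 ± 0.18, SE), Ncapg2 (1.41 ± 0.31), Gm6936 (-2.15 ± 0.53) and Hells (1.86 ± 0.47), at adjusted p of 0.568 or more. Of these genes, Gm6936 lies 960.7 kb from Cip2a, and whether strain alleles linked to Cip2a account for its value was not tested.

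In glands taken 2 weeks after DMBA, p53 target genes had slightly higher values in Cip2a-/- than in WT, with a median log2 fold change of 0.44, 24 of 25 genes positive and scores that overlapped. Milk protein genes had lower values (median -3.02), with a score from -2.04 to 3.16 among the WT glands, and B cell markers had higher ones (median 4.19), while the B cell score ranged from -3.17 to 2.48 among the Cip2a-/- glands. Without WT 2-week library 1 the score difference went from 0.53 to 0.29 for p53 targets and from -1.79 to -0.30 for milk proteins, and without Cip2a-/- 2-week library 2 it went from 2.10 to 0.80 for B cells. Camera called these lists (adjusted p = 9.40e-07, 1.11e-06 and 5.88e-07), with adjusted p = 0.858 with an estimated correlation for each. Cip2a was the 1 gene called by edgeR, with 377 genes at an unadjusted p under 0.05, and DESeq2 called 3 and voom 1. Leaving out any 1 of the 6 libraries except Cip2a-/- library 2 ended the call of Cip2a, with 0 genes called. Ifi202b, an interferon-inducible gene of the Ifi200 family, stood at 12.9 ± 3.24 CPM in WT and 0.0564 ± 0.0978 CPM in Cip2a-/- glands (adjusted p = 1.00). Its level was not low in all Cip2a-/- glands of the other groups, as given below. Rgl3 (log2 fold change -0.85 ± 0.19), Atp6v0e2 (0.75 ± 0.17) and Podxl2 (1.25 ± 0.30) also had small p values without passing.

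At the endpoint, Cip2a-/- glands had lower values of S phase genes (median log2 fold change -0.57), G2 and M phase genes (-0.78) and nuclear genes of oxidative phosphorylation (-0.90), with all 27 of the last group negative. T cell, B cell and skeletal muscle genes had medians of -3.95, -5.02 and -6.77, and luminal progenitor and milk protein genes of 1.15 and 2.04. The oxidative phosphorylation score was 1.43, -0.61 and 0.40 in the WT glands and 0.13, -0.10 and -0.79 in the Cip2a-/- ones. In the same order the slope of expression on transcript length, per doubling of length, was -0.11, -0.03 and -0.16 in WT and -0.13, -0.02 and -0.04 in Cip2a-/-. The 3 glands with the steepest slopes thus had the highest of these scores, and how far the trend enters them was not tested. WT endpoint library 1 carried much of the list differences: its T cell, B cell and muscle scores were 3.73, 5.10 and 5.54, and its luminal progenitor score -3.73. WT library 2 had -1.18, -2.54, -4.95 and 1.39, within or below the range of the Cip2a-/- glands for the first 3. The S phase score was 0.30 to 0.60 in the 3 WT glands and -0.75 to 0.10 in the 3 Cip2a-/- ones, whereas the G2 and M score was -2.35 in Cip2a-/- library 2 and overlapped otherwise. Without WT endpoint library 1 the score differences went from -0.66 to -0.15 for oxidative phosphorylation, from -1.76 to -0.17 for T cells, from -2.62 to -0.68 for B cells, from -3.70 to -1.12 for muscle and from 2.15 to 0.79 for luminal progenitors. Without Cip2a-/- endpoint library 1 that of milk proteins turned from 1.49 to -0.43, and without Cip2a-/- endpoint library 2 those of the S phase and the G2 and M lists went from -0.74 to -0.49 and from -1.20 to -0.28. Camera called all of these lists, with adjusted p from 5.41e-09 for the S phase and oxidative phosphorylation lists to 0.00175 for the milk list. Each call was lost when the correlation was estimated, where adjusted p = 0.509 with an estimated correlation for all 8. Over the B cell list alone, 14 of 15 genes were called lower, and over all genes 0 of them. Cip2a was the 1 gene called by edgeR, with 1659 genes at an unadjusted p under 0.05, DESeq2 called 89 and voom 0. Without WT endpoint library 1 or Cip2a-/- endpoint library 1 or 3 edgeR called 0 genes, and without WT library 2 it called 6. The next genes by p were Vit (2.62 ± 0.49), the basement membrane collagen gene Col4a4 (1.98 ± 0.40), the glycosyltransferase gene Mgat3 (1.55 ± 0.31) and P2rx1 (1.32 ± 0.27), each at an adjusted p of 0.458.

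Averaged over the 3 conditions, the 3 genes with the smallest p after Cip2a lay near it on chromosome 16: Dzip3 at 15 bp, Cd47 at 832 kb and Ift57 at 679.6 kb. Dzip3, an E3 ubiquitin ligase gene, was lower in Cip2a-/- glands (log2 fold change -1.24 ± 0.19, SE). Cd47, which encodes an inhibitory ligand for macrophages, was higher (0.62 ± 0.11), as was Ift57, a gene of intraflagellar transport (0.60 ± 0.15). Tagln3, 3269.6 kb away, was lower (-1.35 ± 0.36). By condition, Ift57 had 0.06 ± 0.25 untreated, 0.69 ± 0.25 at 2 weeks and 1.06 ± 0.26 at the endpoint. Tagln3 had -1.85 ± 0.65, 0.04 ± 0.60 and -2.24 ± 0.65 in the same order. These 2 averages thus hide a condition with almost no difference, whereas Dzip3 and Cd47 kept their direction in all 3 conditions. Averaged over the conditions, Dzip3, Cd47, Ift57 and Tagln3 passed when adjusted over the 65 genes tested within 10 Mb (adjusted p = 0.000977, 0.00225, 0.0214 and 0.0362). None of these 4 genes passed over all genes (adjusted p from 0.116 upward). Over the fixed list of 49 tested genes near Cip2a, 2 were called higher and 2 lower adjusted over the list alone, and camera did not call the list (adjusted p = 0.0903). Within 10 Mb, 11 of 65 genes (16.9%) had an unadjusted p under 0.05, against 130 of 15416 other genes (0.843%), an odds ratio of 23.9 (Fisher exact test, p = 1.42e-11), a threshold chosen after the data were seen. The fixed test on called genes had no call to count, with 0 of 65 near and 0 elsewhere (Fisher exact p = 1), and by DESeq2 2 of 87 genes near Cip2a and 0 elsewhere were called (Fisher exact p = 1.96e-05). These Fisher tests count genes of the same glands, which are not independent, so their p values do not measure spread between animals. The background was also low, since 142 of all genes had an unadjusted p under 0.05 against 774 expected by chance, which raises the odds ratio. The counting of reads between Dzip3 and Cip2a could not be checked, since the strand setting is not given. The mice had a mixed strain background, and the strain alleles near Cip2a are not given in the sources used here. Whether the differences near Cip2a come from its loss or from strain alleles linked to it was not tested. In all, edgeR called 1 gene, Cip2a, with 142 at an unadjusted p under 0.05, DESeq2 called 3 and voom 1. Without WT untreated library 1 edgeR called 2 genes.

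**Figure D3:**
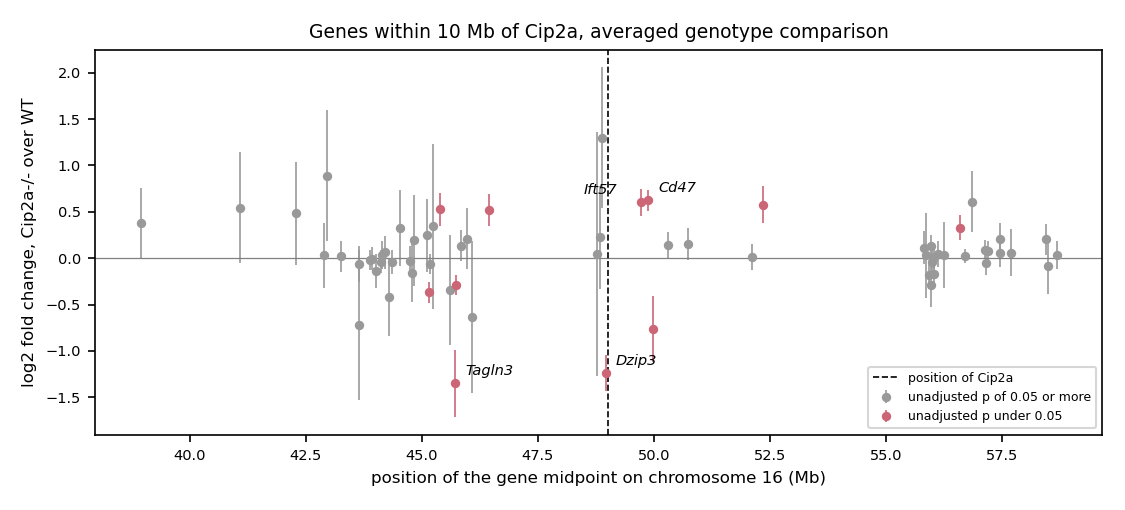
Log2 fold change of Cip2a-/- over WT averaged over the 3 conditions (y axis) for the 65 genes tested within 10 Mb of Cip2a, by position on chromosome 16 in Mb (x axis). Points are estimates, bars 1 SE and the dashed line marks Cip2a. The 11 genes with an unadjusted p under 0.05, in red, include Dzip3 at -1.24 and Cd47 at 0.62.

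PP2A subunit and inhibitor genes did not move with genotype as a list. Their median log2 fold change between the genotypes averaged over conditions was 0.02 over 20 genes (camera adjusted p = 0.425), and camera called this list in none of the 13 comparisons.

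At 2 weeks after the last DMBA dose, p53 target genes were higher than in untreated glands in both genotypes. The median log2 fold change of the 25 genes was 0.72 in WT with 23 positive, 1.22 in Cip2a-/- with 24 positive, and 1.03 over both with 24 positive. Gdf15, a stress cytokine gene, rose from 0.522 ± 0.119 and 0.459 ± 0.362 CPM in untreated WT and Cip2a-/- glands (SD, n = 3) to at least 4.33 CPM in each WT gland and to 19.7 ± 5.95 CPM in Cip2a-/-, a log2 fold change of 4.99 ± 0.53 (SE) over both genotypes. Ephx1, which is not on the p53 list and encodes the microsomal epoxide hydrolase that takes part in the metabolism of polycyclic hydrocarbons, rose with a log2 fold change of 1.23 ± 0.17. Members of the p53 list beside Gdf15 had large values that passed only over the list: Cdkn1a, the cell cycle inhibitor p21, at 3.34 ± 0.57, the receptor gene Eda2r at 3.08 ± 0.54, Zmat3 at 1.48 ± 0.25, the apoptosis gene Bax at 1.11 ± 0.21, and Mdm2, which encodes the ubiquitin ligase for p53, at 1.03 ± 0.21. Pmaip1 was the member with a negative value, at -0.57 ± 0.62.

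Camera called the p53 list over both genotypes (adjusted p = 4.16e-42) and in Cip2a-/- (adjusted p = 2.81e-38), and these calls held with an estimated correlation (adjusted p = 0.00276 and 0.00325) and with fry (adjusted p = 0.00359 and 0.00897). In WT alone the camera call (adjusted p = 5.09e-16) was lost, with adjusted p = 0.121 with an estimated correlation. Over both genotypes 18 of 25 genes were called higher adjusted over the list alone and 1, Gdf15, over all genes. The corresponding counts adjusted over the list alone were 11 in WT and 17 in Cip2a-/-. The list's score was between 0.01 and 1.47 in the 6 treated glands and between -0.67 and -0.19 in the 6 untreated ones. The exact permutation p within genotypes was 0.005, the smallest that 400 arrangements can give, and 0.24 after adjustment over 48 lists. The difference between the genotypes in this response had a median of 0.47 (camera adjusted p = 4.35e-04; adjusted p = 0.919 with an estimated correlation). Without WT 2-week library 1 the score difference for it went from 0.48 to 0.25. Without WT 2-week library 3 the median in WT was 0.39.

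**Figure D4:**
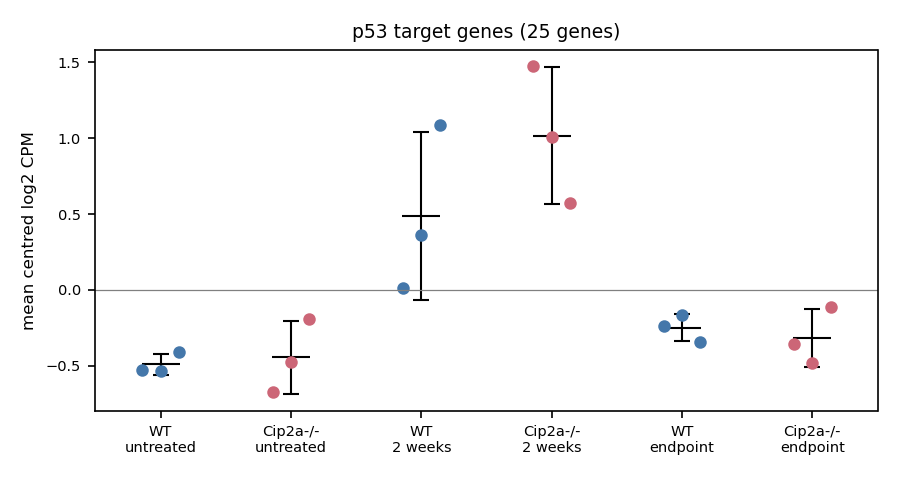
Score of 25 p53 target genes per library, as the mean of centred log2 CPM (y axis), by group (x axis). Points are libraries, marks are means and bars 1 SD (n = 3). The 6 glands taken 2 weeks after DMBA lie between 0.01 and 1.47, above the 12 others, which lie between -0.67 and -0.11.

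Other groups of genes moved at 2 weeks without a call that held. Markers of lymphoid and mast cells had lower values over both genotypes, with medians of -3.25 for B cells, -1.45 for T cells, -1.86 for plasma cells and -1.12 for mast cells, and the adjusted p with an estimated correlation was 0.414 for B cells, plasma cells and mast cells and 0.639 for T cells. The lymph node stroma score was lower too, by a score difference of -1.31 beside -2.41 for B cells (exact permutation p within genotypes 0.14 and 0.085). Without Cip2a-/- untreated library 3 the T cell score difference went from -1.19 to -0.74. Macrophage genes had a median of 0.02 and were not called (camera adjusted p = 0.716). Adjusted over the list alone, 5 of 8 plasma cell genes were called lower, with 0 over all genes. Ribosomal protein genes had a median of -0.32 with 3 of 82 positive (camera adjusted p = 5.71e-18; adjusted p = 0.581 with an estimated correlation). The slope of expression on transcript length was 0.01 to 0.14 per doubling of length in the 2-week libraries and -0.10 to 0.10 in the untreated ones. How far this trend enters the list was not tested. Genes induced through the aryl hydrocarbon receptor had a median of 0.07 over 11 genes and were not called (camera adjusted p = 0.475), and its classical target Cyp1a1 had a log2 fold change of 0.74 ± 0.79.

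By gene, edgeR called 0 genes in WT at 2 weeks, with 655 at an unadjusted p under 0.05, while DESeq2 called 14 and voom 528. In Cip2a-/- it called 2, Gdf15 (log2 fold change 5.40 ± 0.76) and Ephx1 (1.76 ± 0.24), both higher in 3 of 3 libraries and at adjusted p = 0.0369, while DESeq2 called 36 and voom 1. Leaving out any 1 of the 6 libraries ended the calls of Gdf15 and Ephx1, with 0 genes called, or 1 other gene called lower without Cip2a-/- 2-week library 2. Over both genotypes, a comparison added after the data were seen, edgeR called 4 genes, Gdf15, Ephx1, Syt17 (2.71 ± 0.41) and C130026I21Rik (-4.89 ± 0.72), with 1017 at an unadjusted p under 0.05, DESeq2 88 and voom 76. Leaving out any 1 of the 12 libraries gave 1 or 2 called genes, apart from 12 called without WT 2-week library 1. The interaction of genotype and DMBA at 2 weeks had 0 edgeR calls and 449 genes at an unadjusted p under 0.05, with 7 by DESeq2 and 13 by voom. Atp6v0e2 had the smallest p there (1.71 ± 0.25, adjusted p = 0.0946), with 54.3 ± 6.13 CPM untreated and 24.8 ± 3.21 CPM at 2 weeks in WT and 27.9 ± 5.74 and 41.8 ± 3.97 CPM in Cip2a-/- glands.

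Whether both genotypes responded alike was compared across genes. At 2 weeks the log2 fold changes of WT and Cip2a-/- glands had a Pearson r of 0.19 and a Spearman rho of 0.14 across 15482 genes, which are not independent replicates. Without Cip2a-/- untreated library 3 r was -0.00519 and rho -0.0439, without WT 2-week library 3 r was 0.0585 and rho 0.0501, and without Cip2a-/- 2-week library 1 r was 0.305. These arms share no library. At an unadjusted p under 0.05 in both, 59 genes were higher in both against 9.30 expected from independent lists, 24 were lower in both against 5.06, and 16 went opposite ways against 15.3. The 59 include 10 of the 25 p53 targets: Bax, Cdkn1a, Eda2r, Gdf15, Mdm2, Polk, Psrc1, Tnfrsf10b, Trp53inp1 and Zmat3. Calls shared at adjusted p were 0, with 0 expected. At the endpoint r was -0.07 and rho -0.01, and r was 0.535 without WT endpoint library 1 and -0.296 without WT endpoint library 2. Here 156 genes were higher in both against 77.9 expected, 140 lower in both against 59.3, and 48 went opposite ways against 136.

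Averaged over the genotypes, endpoint glands had lower values of extracellular matrix genes than untreated glands and higher values of stress-inducible early genes. Gadd45g, a gene induced by stress and DNA damage, rose with a log2 fold change of 1.76 ± 0.24 over both genotypes, as did the early response gene Ier3 (1.15 ± 0.21) and Ppp1r15a (1.05 ± 0.19), which encodes the GADD34 subunit that directs a phosphatase to the translation factor eIF2α. Among the genes that fell were Abi3bp (-1.59 ± 0.17), which encodes a matrix protein, the aggrecan-cleaving protease gene Adamts5 (-1.67 ± 0.30), the secreted guidance factor gene Sema3c (-1.58 ± 0.23), the channel gene Trpv1 (-1.81 ± 0.31), Nap1l5 (-1.95 ± 0.33) and the transporter gene Slc38a11 (-3.13 ± 0.53). Fibroblast and matrix genes had a median of -0.86 with 0 of 20 called lower over all genes and 9 adjusted over the list alone. Immediate early genes had a median of 0.69 with 2 of 23 called higher, and 10 higher and 1 lower adjusted over the list alone. Within Cip2a-/- both scores overlapped. That of matrix genes was -1.16 to -0.01 at the endpoint and -0.34 to 0.51 untreated, and that of early genes 0.01 to 0.65 and -0.74 to 0.10. In WT neither overlapped, and the lowest matrix score, -2.28, was that of WT endpoint library 1. Erythroid genes had a median of 2.91, 0 of 6 called over all genes and 6 higher adjusted over the list alone, with a score of 5.14 in Cip2a-/- endpoint library 3 against -0.87 to 1.99 in the 5 other endpoint glands. Without that library the score difference went from 1.51 to 0.57. Ribosomal protein genes had a median of 0.46, 0 of 82 called over all genes, and 66 higher and 1 lower adjusted over the list alone.

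Camera called these 4 lists over both genotypes (adjusted p = 1.88e-09, 1.71e-08, 0.000709 and 3.56e-23), and the adjusted p with an estimated correlation was 0.645, 0.645, 0.936 and 0.936. In this added comparison edgeR called 39 genes, 4 higher and 35 lower, with 2617 at an unadjusted p under 0.05, DESeq2 828 and voom 3. The count fell to 2 without WT untreated library 3 and reached 279 without WT endpoint library 1 and 226 without Cip2a-/- endpoint library 1. Of 60 splits of the libraries 4, the real one included, gave as many genes, and the highest other count was 708. Offsets, covariates and joint omissions also moved the count widely, as given below.

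Within WT, 5 genes fell at the endpoint: Abi3bp (-1.95 ± 0.24), Matn2 (-2.04 ± 0.31), which encodes matrilin 2 of the matrix, Thbd (-1.76 ± 0.25), which encodes the anticoagulant receptor thrombomodulin, Atp6v0e2 (-1.26 ± 0.18) and the uncharacterised Gm6936 (-5.29 ± 0.65), with adjusted p from 0.00721 to 0.0378 in edgeR and lower levels in 3 of 3 libraries. Abi3bp went from 40.0 ± 7.24 to 10.4 ± 2.25 CPM and Thbd from 204 ± 19.8 to 60.3 ± 20.5 CPM. Gm6936 lies 960.7 kb from Cip2a, and whether strain alleles there differ among the WT glands was not tested. At an unadjusted p under 0.05 there were 1865 genes, and DESeq2 called 306 and voom 17. Leaving out WT endpoint library 1 left 0 calls, WT untreated library 1, 2 or 3 left 3, 1 or 2, WT endpoint library 2 gave 46 and WT endpoint library 3 gave 8. In Cip2a-/- edgeR called 0 genes, with 2268 at an unadjusted p under 0.05, DESeq2 277 and voom 0, and 9 were called without endpoint library 1. The smallest p values belonged to the drug transporter gene Abcc1 (-0.75 ± 0.12), Tram2 (-1.32 ± 0.22), Gadd45g (1.89 ± 0.34), Tbl1x (-1.66 ± 0.31) and Abi3bp (-1.23 ± 0.23), each at adjusted p = 0.201. Cholesterol synthesis genes had a median of -0.88 in Cip2a-/- endpoint glands, with 4 of 20 called lower adjusted over the list alone and 0 over all genes (camera adjusted p = 4.68e-08; adjusted p = 0.712 with an estimated correlation). Their score was 0.15, -0.54 and -1.63 in these glands and -0.01 to 0.70 in untreated Cip2a-/- ones, and the score difference went from -1.02 to -0.54 without Cip2a-/- endpoint library 3.

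For the interaction of genotype and DMBA at the endpoint, 4 of the 5 genes with the smallest p, Hells, Dscc1, Pole and Ncapg2, act in the cell cycle. S phase genes had a median interaction of -1.35 with 18 of 30 called lower adjusted over the list alone and 0 over all genes, and G2 and M genes had a median of -2.18. Examples are Hells (-3.54 ± 0.66), Dscc1 (-3.14 ± 0.67), a gene for loading the replication clamp, and Pole (-2.37 ± 0.51), the leading strand DNA polymerase. Pole stood at 11.1 to 12.2 CPM in the 3 WT endpoint glands and at 2.96 to 6.64 CPM in the 3 Cip2a-/- ones, and at 4.80 to 7.33 CPM in untreated WT and 6.22 to 17.3 CPM in untreated Cip2a-/- glands. The untreated Cip2a-/- glands differed among themselves in both lists, as given above. Without Cip2a-/- endpoint library 2 the score difference of the G2 and M list went from -2.10 to -1.18. Camera called both lists (adjusted p = 3.44e-17 and 3.53e-15), with adjusted p = 0.499 with an estimated correlation for each. EdgeR called 0 genes for this interaction, with 1553 at an unadjusted p under 0.05, DESeq2 34 and voom 0.

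Between the endpoint and 2 weeks after DMBA, averaged over the genotypes, the glands differed in 2067 genes, 13.4% of those tested. Of the ribosomal protein genes 72 of 82 were called higher and 1 lower, with a median log2 fold change of 0.79 (adjusted p = 0.527 with an estimated correlation). With offsets for transcript length and GC content, which the calls of this comparison follow, the median was 0.66 with 64 called higher and 1 lower. Examples are Rpl3 (1.03 ± 0.18, SE) and Rpl28 (1.01 ± 0.18). Genes of fibroblasts and their matrix fell, 13 of 20 with a median of -1.44, among them the collagen genes Col3a1 (-2.78 ± 0.57) and Col6a3 (-2.17 ± 0.37) and the proteoglycan gene Lum (-2.17 ± 0.44). With length offsets 7 of the 20 matrix genes were called lower, and with both offsets 9, at a median of -1.37. Of the 25 p53 targets 11 were called lower at the endpoint, each of them higher at 2 weeks adjusted over the list alone, including Gdf15 (-3.57 ± 0.49), Eda2r (-2.90 ± 0.54) and Ccng1 (-1.91 ± 0.46), with a median of -0.999. The same 2-week libraries stand in both comparisons of the p53 list. Over both genotypes, the p53 score at the endpoint lay between -0.48 and -0.11, against -0.67 to -0.19 in untreated glands.

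Named genes with the largest increases were Ngp (7.83 ± 1.68), a granule protein gene of neutrophils, Madcam1 (3.09 ± 0.57), an adhesion molecule of vessels that lymphocytes home to, the glucose transporter gene Slc2a3 (2.95 ± 0.63), the metallothionein gene Mt2 (2.88 ± 0.56), Fkbp5 (2.82 ± 0.50), a target of the glucocorticoid receptor, and Cabp4 (2.77 ± 0.64). Fkbp5 reached 232 to 432 CPM in 4 of 6 endpoint glands and 37.6 and 49.9 CPM in the first library of each genotype, against 22.1 to 57.3 CPM in the 12 other glands. Among those with the largest decreases were Tph2 (-4.30 ± 0.69), the translation regulator gene Cpeb4 (-3.37 ± 0.63), Prnd (-3.20 ± 0.56) and Megf9 (-2.85 ± 0.46), beside Gdf15. For Cpeb4 the highest level, 32.8 CPM, was that of the muscle-rich Cip2a-/- 2-week library 1. Neutrophil genes were called higher in 7 of 11, with Camp at 7.16 ± 1.72 and S100a9 at 5.36 ± 1.17, and erythroid genes in 5 of 6, with Slc4a1, the red cell anion exchanger, at 5.33 ± 1.38. S100a9 ranged from 0.758 to 156 CPM among the 6 endpoint glands, and Slc4a1 was highest, at 266 CPM, in Cip2a-/- endpoint library 3. Without that library the erythroid score difference went from 1.85 to 0.91.

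For the smaller lists the background is the called share of all genes tested, 13.4% with both directions together (992 higher and 1075 lower of 15482). Immediate early genes were called higher in 6 of 23, with Ier3 at 1.24 ± 0.21 and Junb at 0.76 ± 0.19, and lower in 1, Nr4a3 (-1.48 ± 0.44). With offsets for length and GC content 4 were called higher. The camera call of this list was lost with GC offsets (adjusted p = 0.0533) and with both (adjusted p = 0.0725), against 0.00861 without. Without Cip2a-/- endpoint library 3 the score differences of the immediate early and the cholesterol synthesis lists went from 0.31 to 0.21 and from -0.68 to -0.44. MYC targets were called higher in 6 of 29 and lower in 1. Of the cholesterol synthesis list 2 of 20 fell, Stard4 (-1.28 ± 0.24) and Hsd17b7 (-0.90 ± 0.24). In the list of genes near Cip2a 11 of 49 fell and 2 rose, with a median of -0.24 that turned to 0.07 under the offsets for length and GC content, and with Retnlg (4.59 ± 0.99) among the higher and Abi3bp (-1.54 ± 0.17) among the lower. In the PP2A list, which camera did not call (adjusted p = 0.768), Igbp1 (0.44 ± 0.11) and Anp32a (0.37 ± 0.12) rose and Ppp2r5e (-0.41 ± 0.10) fell. These named members of lists not called were chosen after their values were seen.

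**Figure D5:**
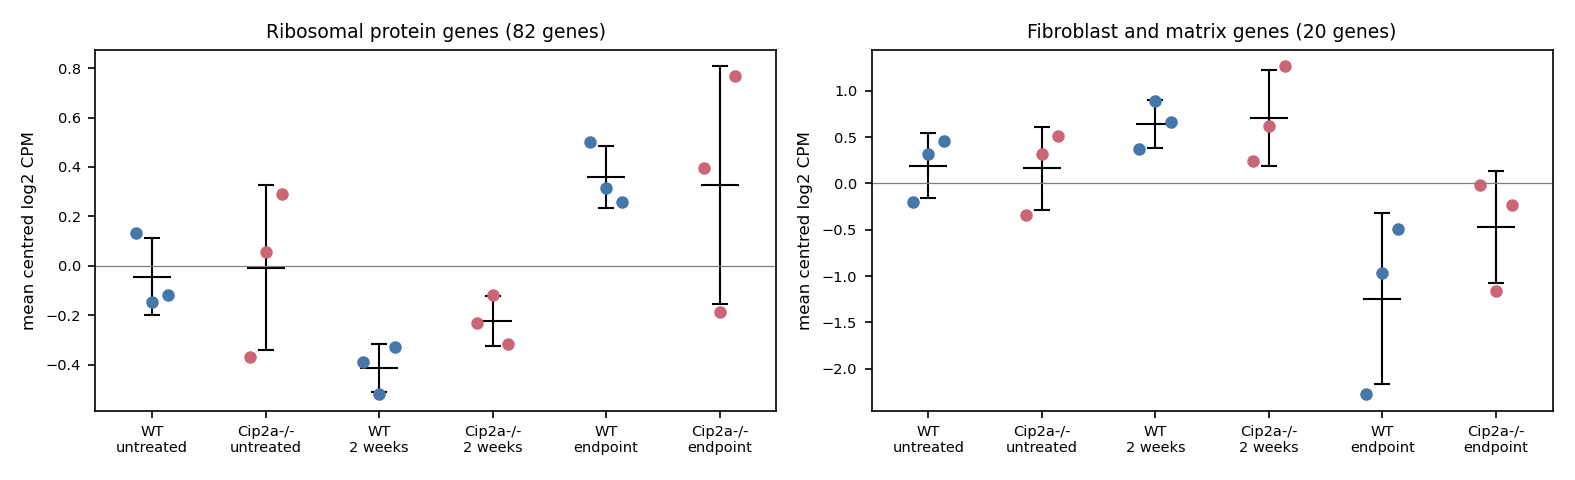
Scores of 82 ribosomal protein genes (left) and 20 fibroblast and matrix genes (right) per library, as the mean of centred log2 CPM (y axis), by group (x axis). Points are libraries, marks are means and bars 1 SD (n = 3). The ribosomal score is -0.52 to -0.12 at 2 weeks and -0.19 to 0.77 at the endpoint, and the matrix score 0.24 to 1.27 and -2.28 to -0.01.

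EdgeR called 992 genes higher and 1075 lower at the endpoint, with 4667 at an unadjusted p under 0.05, DESeq2 3245 and voom 1726. Adjusted over the list alone, 74 ribosomal protein genes were called higher and 1 lower, 15 matrix genes lower and 17 p53 targets lower and 1 higher. Camera called 11 lists. The adjusted p with the preset and with an estimated correlation was 1.87e-36 and 0.527 for ribosomal protein genes, 1.08e-12 and 0.499 for matrix genes, 3.26e-10 and 0.499 for p53 targets, and 0.00436 and 0.903 for neutrophil genes. Fry called 4 lists, those of ribosomal protein genes (adjusted p = 0.00751), matrix genes, p53 targets and genes near Cip2a (each adjusted p = 0.00488). The genes called higher had shorter and GC-richer transcripts than those called lower, with medians of 2458 nt and 54.4% GC against 4987 nt and 45.3%, and with offsets for both properties 1286 genes were called, 64.5% of them higher against 48.0% without offsets. Without single libraries the count was 978 (WT 2-week library 2), 1068 (WT 2-week library 3), 1237 (WT 2-week library 1), 1182 (Cip2a-/- 2-week library 1) and 1203 (Cip2a-/- endpoint library 3). It was lower still in a fit to only the groups in the contrast, as given below.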

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

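The tests on length and GC content together, the sizes of the changes under offsets, both tests on Xist and every test on the 2 comparisons with untreated glands averaged over genotypes were chosen after the result was seen.

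For 5 gene lists camera called the interaction of genotype and DMBA at the endpoint, with at least 1 member past the threshold adjusted over the list alone, but no other list test called them. S phase genes controlled by E2F factors had a median interaction of -1.35 and DNA damage repair genes of -1.04, with 18 and 11 members called lower adjusted over the list alone. Brown adipocyte genes had a median of -4.23 with 3 called lower, dendritic cell genes of -1.66 with 1 called lower, and genes induced through the aryl hydrocarbon receptor of 0.30 with 1 called higher. For each of the 5 the camera call was lost, with adjusted p = 0.499 with an estimated correlation, and fry called 0. The brown adipocyte score was 4.25 in WT endpoint library 1 and -2.51 and -1.55 in the other 2 WT glands, and Cip2a-/- untreated library 1 had an S phase score of -0.60 against 0.77 and 0.87 in the other 2, so single glands weigh on these values. Without WT endpoint library 1 the score difference turned from -2.01 to 0.09 for brown adipocytes and went from -1.59 to -0.82 for dendritic cells. EdgeR called 0 genes over all genes, with 1553 at an unadjusted p under 0.05, DESeq2 34 and voom 0.

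The p53 target genes were higher 2 weeks after DMBA, with a median log2 fold change of 1.03 over both genotypes. With muscle, B cell and luminal progenitor scores as covariates the median was 0.82, which argues against composition in those scores as the whole cause. The median was above 100% of 10000 random lists matched on length, GC content and expression, whose highest was 0.22. Of 60 splits 1, the real one, gave a median as large in size, and the highest other was 0.80. A response to DMBA may explain the values as a hypothesis, while batch, age and vehicle, not given in the sources used here, stay open. The header numbers of the 2-week libraries lie apart from all others, so a batch that goes with them could not be told apart from DMBA.

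Between the endpoint and 2 weeks 2067 genes were called, and the shorter, GC-richer transcripts were higher. With offsets for length 1257 of them were called in the same direction and with offsets for GC content 1132, which argues against either alone as the whole cause. With both together 946 were, under 0.5 of the 2067. By the rule set for this test, that goes with length and GC content together as a cause. The median size of the log2 fold change of the 2067 genes was 0.74 (median SE 0.18) without offsets and 0.55 (0.16) with both. In the 1121 genes no longer called it went from 0.62 (0.16) to 0.36 (0.15), so these calls ended as the changes shrank, not as the spread grew. Under both offsets 1727 of the genes kept their sign and at least 0.5 of their size. A shared trend with length and GC content, as from RNA quality or library preparation, may account for these changes, and how far stays open. A real change that follows length or GC content would shrink in the same way and stays open. With the composition scores 1248 genes were still called, and 2061 kept their sign and at least 0.5 of their size, which argues against composition in those scores. The design gives time since DMBA and tumour burden as biological explanations, neither of which could be separated from a batch. The header numbers, higher in every 2-week library than in any endpoint library, part the same groups.

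Xist had 16 reads, 0.886 CPM, in WT untreated library 3 against 286 to 1002 CPM in the 17 other libraries. It was the 1 library with Y-linked reads, 26 against 0 in each of the others, but these came to 0.556% of the reads of their X-linked partners, which argues against a wholly male sample and leaves the source of the 26 reads open. The 8 genes that escape X inactivation had a median log2 ratio of -0.44, where random lists of X-linked genes gave -0.18 to 0.20. The same median in the 17 other libraries ran from -0.37 to 0.44, close to it at the lower end, and Mid1 went the other way at 0.54. A single X chromosome may explain the values but is only weakly set apart by them, and no biological explanation from the design was tested.

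Other splits of the same libraries were counted for each comparison. With 3 libraries against 3 the 10 splits are too few for a share under 0.05. The real count and the highest other were 0 and 0 between the genotypes untreated (10 splits as large), 1 and 0 at 2 weeks (1 split), 1 and 1224 at the endpoint (7 splits), 0 and 0 for DMBA at 2 weeks in WT (10 splits), 2 and 0 in Cip2a-/- (1 split), 5 and 2 at the endpoint in WT (1 split), and 0 and 1 in Cip2a-/- (10 splits). The split with 1224 genes set Cip2a-/- endpoint library 1 with WT endpoint libraries 1 and 3 against the others, which points to a structure of the samples other than genotype. The slope of expression on transcript length, per doubling of length, was -0.16 to -0.11 in those 3 libraries and -0.04 to -0.02 in the others. This split therefore also parts the endpoint glands by that slope, while their slopes on GC content overlapped between its sides. Whether the length trend accounts for the 1224 genes was not tested.

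For the averaged comparisons 60 splits were made. The shares of splits were not adjusted over the comparisons. For the endpoint against 2 weeks 1 split, the real one, was as large (2067 called, highest other 24), which argues against chance. For DMBA at 2 weeks the share also argues against chance (4 called, highest other 0, 1 split), but on few genes. Without any 1 of the 12 libraries the count there was 1 or 2, apart from 12 without WT 2-week library 1. Chance stays open for the count at the endpoint against untreated (39 called, highest other 708, 4 splits). For genotype the count of 1 was reached by 3 splits (highest other 1), but the gene called is Cip2a, with 0 or 1 read in each of the 9 Cip2a-/- libraries and 15 or more in each of the 9 WT ones. For the interactions, with 0 called at 2 weeks (highest other 1) and at the endpoint (highest other 33), all 60 splits are as large by construction, so the count says nothing about chance. EdgeR had 449 and 1553 genes there at an unadjusted p under 0.05, DESeq2 called 7 and 34 and voom 13 and 0. The 708 genes of another split again point to a structure of the samples.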

How the results depend on the processing

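The composition scores, length and GC offsets, joint omissions, score differences without single libraries, the unadjusted threshold near Cip2a and the 2 comparisons with untreated glands averaged over genotypes were chosen after the data were seen. Values were counted for named genes that were called or had the smallest p, for Cip2a between genotypes and for the p53 list. Of these values 1579 kept their direction and side of the threshold, 198 lost a call, 46 gained one and none changed direction. Under the length and GC offsets only the p53 list was counted, so these numbers do not show how single genes held there. Among the other values, the correlations of the DMBA effects changed sign, as did the median of the genes near Cip2a between the endpoint and 2 weeks (-0.24, and 0.07 with both offsets). With 1 library left out, so did the score differences of milk proteins between genotypes at the endpoint (1.49, and -0.43 without Cip2a-/- endpoint library 1), of brown adipocytes in the endpoint interaction (-2.01, and 0.09 without WT endpoint library 1), of macrophages for DMBA at 2 weeks averaged (0.04, and -0.08 without Cip2a-/- untreated library 2) and of the PP2A list between the endpoint and 2 weeks (-0.01, and 0.02 without Cip2a-/- 2-week library 1). The balance of called genes between the endpoint and 2 weeks turned from more lower to more higher with the offsets. The cause was not tested for any change below, except that omissions and fits to the groups in a contrast use fewer libraries.

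DESeq2 called 6 genes between genotypes untreated, 3 at 2 weeks, 89 at the endpoint and 3 averaged, where edgeR called 0, 1, 1 and 1. It called 14 for DMBA at 2 weeks in WT, 36 in Cip2a-/- and 88 averaged (edgeR 0, 2 and 4), 306, 277 and 828 at the endpoint (edgeR 5, 0 and 39), 3245 for the endpoint against 2 weeks (edgeR 2067), and 7 and 34 for the interactions (edgeR 0 and 0, with 449 and 1553 at an unadjusted p under 0.05). Cip2a in untreated glands passed with DESeq2, at a log2 fold change of -5.23. Voom with quality weights called 0 between genotypes at the endpoint, 528, 1 and 76 for DMBA at 2 weeks in WT, Cip2a-/- and averaged, 17 at the endpoint in WT and 3 averaged, and 13 for the interaction at 2 weeks.

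With 1 surrogate variable edgeR called 0 genes between genotypes at 2 weeks and 0 at the endpoint, 26 for the DMBA endpoint in WT and 149 averaged, 10 at 2 weeks averaged and 1 for the interaction at 2 weeks. With composition scores it called 0 and 0 between genotypes at 2 weeks and the endpoint, 0 for DMBA at 2 weeks in Cip2a-/-, 1 averaged, and 168 at the endpoint averaged. Without the 2 muscle-rich libraries these were 0, 0, 0, 1 and 535, with 0 at the endpoint in WT. Without those 2 and WT untreated library 3 they were 0 and 0 between genotypes, 0 for DMBA at 2 weeks in Cip2a-/-, 0 averaged, 0 at the endpoint in WT, and 1114 for the endpoint against 2 weeks. Fits to only the groups in the contrast gave 0 and 0 between genotypes, 0 at 2 weeks in Cip2a-/-, 0 at the endpoint in WT, 4 averaged, and 605 for the endpoint against 2 weeks.

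Length offsets gave 2 genes for genotype averaged, 3 at the DMBA endpoint in WT, 8 at 2 weeks averaged and 7 at the endpoint averaged. GC offsets gave 2, 13 at 2 weeks averaged and 122 at the endpoint averaged. Both gave 2, 12, 24 and, for the endpoint against 2 weeks, 1286. In that comparison 64.3% of called genes were higher with length offsets, 61.6% with GC offsets and 64.5% with both, against 48.0% without.

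The replicate numbers do not pair: 0 of 9 pairs of groups had every correlation above 0.1, and correlations ran from -0.468 to 0.660. With the numbers as a block 20 genes were called at the DMBA endpoint in WT and 60 averaged.

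Camera called 18, 15, 29 and 16 lists between genotypes untreated, at 2 weeks, at the endpoint and averaged, and 0 with an estimated correlation and 0 with fry in each. For DMBA at 2 weeks it called 15 in WT, 26 in Cip2a-/- and 20 averaged, with 0, 1 and 1 under an estimated correlation and 0, 1 and 1 by fry. At the endpoint it called 16, 21 and 15, with 0 by both, and for the interactions 14 and 28, with 0 by both. For the endpoint against 2 weeks it called 11, with 0 under an estimated correlation and 4 by fry. Near Cip2a, DESeq2 called 2 genes and 11 had an unadjusted p under 0.05, against 0 called by edgeR.

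Leaving out 1 library gave 0 to 0 genes between genotypes untreated, 0 to 1 at 2 weeks, 0 to 6 at the endpoint and 1 to 2 averaged. For DMBA at 2 weeks it gave 0 to 0 in WT, 0 to 1 in Cip2a-/- and 1 to 12 averaged, at the endpoint 0 to 46 in WT, 0 to 9 in Cip2a-/- and 2 to 279 averaged, and 0 to 1 for each interaction. For the endpoint against 2 weeks it gave 978 (without WT 2-week library 2) to 2610 (without WT endpoint library 1). The lists called ran from 13 to 24, 8 to 17, 16 to 29 and 9 to 24 between genotypes, 13 to 18, 18 to 27 and 18 to 23 for DMBA at 2 weeks, 14 to 22, 19 to 24 and 12 to 17 at the endpoint, 13 to 19 and 15 to 31 for the interactions, and 9 to 20 for the endpoint against 2 weeks. The correlation of the DMBA effects in WT and Cip2a-/- ran from -0.00519 to 0.305 at 2 weeks (rho -0.0439 to 0.252) and from -0.30 to 0.53 at the endpoint (rho -0.22 to 0.46).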

Other observations

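All values in this part were chosen after the data were seen. Ifi202b had 0 reads in Cip2a-/- untreated library 2 and in Cip2a-/- 2-week libraries 1 and 3, 0.169 CPM in Cip2a-/- 2-week library 2, and 2.53 to 16.4 CPM in the 14 other libraries. Whether these Ifi202b levels follow strain alleles on the mixed background was not tested. Gdf15 was between 4.33 and 25.4 CPM in the 6 glands taken 2 weeks after DMBA and between 0.179 and 4.17 CPM in the 12 others. Cdkn1a was between 139 and 1081 CPM at 2 weeks, and at 496 CPM in Cip2a-/- endpoint library 3.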
